A study of Homo sapiens with 28 samples.

How the data were processed

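The study sequenced RNA from WT and CCR7-knockout H9 cells in 4 cell types, and the deposited values for 28 libraries were used. Per the labels, RNA was extracted with a column kit, converted to cDNA and sequenced in pairs of reads. The authors aligned reads to hg38 with STAR 2.5.4b and assigned them to genes with Subread and featureCounts 1.4.6, and the labels state neither the annotation nor the strand setting. The deposited values are counts, whole numbers of reads per gene symbol without normalization, for 24133 genes, each with at least 6 counts summed over the libraries. The other unit, per the file headers, is the length of the gene model in bases (28 to 205012), which served only in the test of length bias. No other column was present.

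Each library was assigned to a cell type and genotype from its title, description, cell type and genotype labels, which were alike. The source name and tissue labels of some libraries differed from these and were not used. Naive groups held 2 libraries and the others 4, and the labels call them biological replicates. Replicates were checked for copies of the same library, and their lowest chi-square per degree of freedom was 12.1, far above counting noise. Totals ranged from 7700959 to 31787978 counts. The biological coefficient of variation was 0.326, and precision was set by the spread between libraries more than by depth.

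Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr over the 8 groups, which left 19497 genes. Libraries were scaled by TMM, and a quasi-likelihood model with a mean for each group was fitted to all libraries jointly. Each comparison was a contrast of group means, and each interaction a contrast of 4 means. The p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The SE of a log2 fold change was its absolute value over the square root of the F statistic. CPM were computed with TMM factors, and log2 CPM with a prior count of 2. A gene without counts in a group was given a bound from a floor of 3 counts summed over that group. All p-values of gene comparisons come from edgeR, and those of lists from camera in limma with an inter-gene correlation of 0.01, with an estimated correlation as the alternative.

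The lists, comparisons, tests and alternatives were chosen before the data were examined, except where stated. There were 30 lists with 494 members, of which 463 were in the table. Named genes followed a rule. For each KO comparison they were CCR7, up to 10 genes with the largest change in each direction, and up to 4 members of each list with the smallest adjusted p, all past the threshold. The large changes also needed a mean log2 CPM of at least 1, a named symbol and every KO library on the same side of every WT library. For WT steps and interactions the number was 5 in each direction, and interactions did not need separated libraries. List members that missed the threshold could be named with their values. Genes of each differentiation step were the 200 with the largest change in each direction in WT cells, with lists of 100 and 500 and lists from separate libraries as alternatives. Overlaps were tested with Fisher's exact test over the genes tested.

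Positions came from GENCODE release 29 and were found for 23607 genes. Arm medians were taken for 39 arms with at least 30 genes and compared with 10000 random gene sets, with arm boundaries in whole Mb. Profiles and values per library used genes with a mean log2 CPM of at least 3, in bins of 5 Mb. The correction for GC content and length was a loess fit.

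The alternatives were RLE factors in edgeR, a Wald test in DESeq2 1.42.0, no filter, a filter of CPM at least 1 in 4 libraries, a term for replicates 1 and 2 against 3 and 4, the replicate number as a replicate block, only the groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. Fits of replicates 1 and 2 or 3 and 4 alone, and fits without genes of 12p, 17p and 19p, were added after seeing the data. The calls were tested on simulated data with 200 changed genes in each comparison. Libraries were also regrouped in all 35 ways for comparisons of 4 against 4, and in 100 drawn ways for interactions between trophoblast types. Dixon's test (critical value 0.829 for 4 libraries) was applied to 35 measures in each of the 6 groups of 4 libraries. Genes of the sex chromosomes were left out of the arm medians, and Y-linked genes and XIST were left out of all tables. Genes of families with near-identical sequences share reads, so their values cannot be assigned to single members with certainty.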

Results

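RNA was sequenced from 28 libraries of H9 cells, an established human embryonic stem cell line, and of trophoblast cells made from them. Wild-type (WT) cells were compared with cells in which CCR7 had been knocked out (KO), in 4 cell types. These were naive embryonic stem cells, human trophoblast stem cells (hTSC) derived from them, and the differentiated progeny of hTSC, extravillous trophoblast (EVT, the invasive cells that anchor the placenta) and syncytiotrophoblast (STB, the fused, hormone-secreting layer of the placenta). Each naive group held 2 libraries and each of the other 6 groups held 4. The labels call the libraries biological replicates and do not say whether they came from separate differentiations. In the descriptions, all KO libraries share a name prefix and all WT libraries share another, so KO may stand for a single line. The spread between libraries then holds no variation between KO lines, and genotype cannot be told apart from line. Total counts ranged from 7700959 to 31787978 per library. The group means were 20019340 for naive WT, 17405536 for naive KO, 13906612 for hTSC WT, 14536977 for hTSC KO, 20843847 for EVT WT, 12300823 for EVT KO, 16101249 for STB WT and 14833489 for STB KO. Cell type was the largest source of variation, with 39.6% of the variance of log2 counts-per-million (CPM) values on the first principal component and 22.8% on the second. A gene was called changed at an adjusted p under 0.05 in edgeR over the 19497 genes tested, and errors were SD across libraries for CPM and SE for log2 fold changes (KO over WT).

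CCR7, the receptor for the chemokines CCL19 and CCL21, was measured first because it was the targeted gene (chromosome 17, 40553769 to 40565472 on hg38, minus strand). In WT cells it rose from naive cells to hTSC, with 6 ± 3.67 CPM in naive cells (n = 2), 200 ± 90.4 in hTSC, 213 ± 91.6 in EVT and 139 ± 71.2 in STB (n = 4 each). In KO cells it fell in every cell type, to 0.335 ± 0.0529 CPM in naive cells, 2.1 ± 1.56 in hTSC, 2.87 ± 0.985 in EVT and 2.47 ± 0.744 in STB. The differences were 17.2-fold in naive cells (adjusted p = 0.0198), 95-fold in hTSC (adjusted p = 9.95e-08), 75.6-fold in EVT (adjusted p = 2.38e-07) and 55.4-fold in STB (adjusted p = 4.4e-07). Every KO library lay below every WT library of its cell type. From 5 to 8 reads per naive KO library and from 14 to 67 per trophoblast KO library were still assigned to the gene. With the naive groups fitted alone, the naive difference was -4.12 on the log2 scale with an adjusted p of 0.136. It also missed the threshold without naive WT replicate 2 (-3.29), without naive KO replicate 1 (-4.29) and without naive KO replicate 2 (-3.95). The ligand genes CCL19 and CCL21 were not in the table analysed here.

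**Figure D1:**
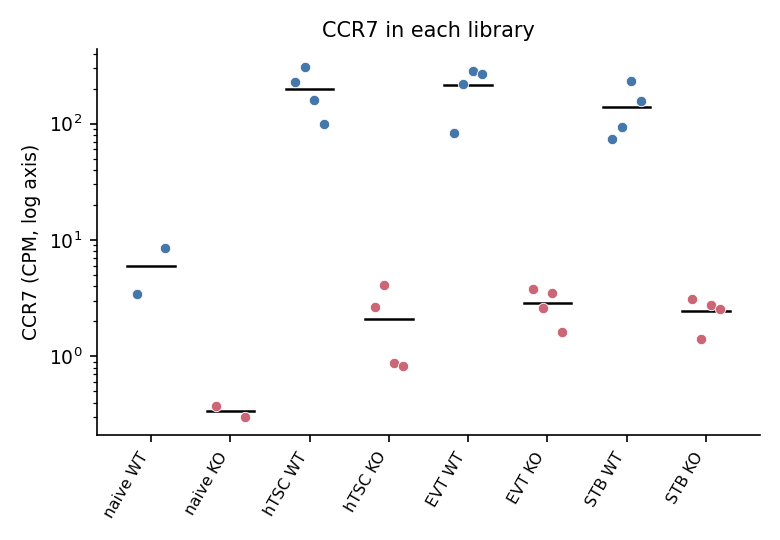
CCR7 in CPM on a log axis, with a point for each library (WT blue, KO red) and a line at the group mean. WT means were 6, 200, 213 and 139 CPM in naive cells, hTSC, EVT and STB, and KO means were 0.335, 2.1, 2.87 and 2.47.

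The comparison of naive KO with naive WT cells asked whether loss of CCR7 changed the starting stem cells. Several trophoblast genes were lower in naive KO cells. GATA2 and GATA3, transcription factors of early trophoblast, fell from 19.4 ± 2.25 to 2.13 ± 0.7 CPM and from 32.7 ± 6 to 6.88 ± 0.968 CPM (n = 2 each, 9.18-fold and 4.74-fold). CGA, the alpha subunit of chorionic gonadotropin, fell 22.7-fold from 1038 ± 305 to 45.8 ± 9.54 CPM, and the placental growth factor PGF fell 21-fold from 51.5 ± 12.6 to 2.44 ± 0.169 CPM. The call of CGA was lost without any of the 4 naive libraries. The transcription factors of pluripotency did not pass the test, with POU5F1 at 491 ± 122 CPM in KO and 482 ± 82.1 in WT cells (log2 fold change 0.03 ± 0.55) and NANOG at 307 ± 32.5 and 239 ± 1.17 (0.36 ± 0.47).

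In all, 62 genes were lower and 0 were higher in naive KO cells, and 782 had an unadjusted p under 0.05. Besides GATA2 and GATA3, the cytotrophoblast list (markers of the stem-like trophoblast layer) included VGLL1 (log2 fold change -2.74 ± 0.39) and EGFR (-2.57 ± 0.42) among its 6 members that fell. Its other 15 members did not pass the test, and 7 fell when adjusted over the list alone. Its median was -0.95 (camera adjusted p = 4.2e-22, and adjusted p = 0.000126 with an estimated correlation). Of 31 syncytiotrophoblast markers, 5 fell and 26 did not pass (15 fell when adjusted over the list alone). A median of -2.07 was found over the whole list (-1.85 with genes without a KO count set at their bound; adjusted p = 4.5e-32, and adjusted p = 0.0121 with an estimated correlation). Those that fell included the steroid enzyme HSD3B1 (-3.36 ± 0.59) and the retroviral envelope genes ERVW-1 (-1.85), ERVV-1 (-5.23 ± 0.96) and ERVV-2 (-4.67), which belong to the family of fusion proteins of the placenta. Of 23 extravillous markers, ITGA5 fell (-2.77) and 22 did not pass (2 fell when adjusted over the list alone). A median of -1.04 was found over the whole list (adjusted p = 3.1e-05, but adjusted p = 0.289 with an estimated correlation). None of the 10 pregnancy-specific glycoprotein genes passed, at either adjustment. A median of -2.56 was found over the whole list (-2.26 with bounds; adjusted p = 4.7e-05, but adjusted p = 0.289 with an estimated correlation). None of the 13 naive pluripotency markers (median 0.20, adjusted p = 0.0984) and none of the 13 general pluripotency markers (median 0.28, adjusted p = 0.173) passed. CD274, which encodes the immune checkpoint ligand PD-L1, had no counts in either KO library and 83 in the WT libraries, which makes it at least 22.5-fold lower from a floor of 3 counts over the KO group. IL36RN, an antagonist of interleukin 36 signalling, was at 0.0764 CPM in KO and 3.56 in WT cells (adjusted p = 0.000402), and CPM, the carboxypeptidase gene, fell as well (-4.30 ± 0.54, and -5.07 without naive KO replicate 1). The calls of ERVW-1 and ITGA5 were lost without any of the 4 naive libraries, those of HSD3B1 and ERVV-1 without either naive KO library, and that of EGFR without naive KO replicate 2. The count of 62 rested on few libraries, at 30 without naive WT replicate 1, 21 without naive WT replicate 2, and 16 without either naive KO replicate 1 or naive KO replicate 2, and it was 20 with the naive groups fitted alone and 128 in DESeq2.

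The comparison in hTSC asked what loss of CCR7 changed in trophoblast stem cells. Of 10 genes for pregnancy-specific glycoproteins, secreted immunoglobulin-like proteins of the syncytiotrophoblast, 8 were lower in KO hTSC. PSG3 fell 12.3-fold, from 117 ± 40.6 to 9.49 ± 3.06 CPM (n = 4 each, adjusted p = 3.1e-05), and PSG6 fell 13.2-fold, from 114 ± 90 to 8.63 ± 3.52 CPM (adjusted p = 3.1e-05). CGA fell 6.64-fold, from 7662 ± 4296 to 1153 ± 1049 CPM (adjusted p = 0.0162), and INHA, the inhibin alpha subunit, fell 15.3-fold (adjusted p = 0.00202). The epithelial adhesion gene EPCAM rose 3.25-fold, from 44.6 ± 29.4 to 145 ± 10.9 CPM (adjusted p = 0.00742), and TEAD4, a transcription factor of trophoblast stem cells, rose 2.21-fold (adjusted p = 0.0411). The log2 fold change of PSG6 was -3.72 and moved to -3.08 without hTSC WT replicate 3. That of INHA moved from -3.94 to -3.19 without hTSC WT replicate 1. CGA had no call without hTSC KO replicate 2, 3 or 4, and TEAD4 had none without hTSC WT replicate 3 or 4 or hTSC KO replicate 2, 3 or 4. TEAD4 lies on 12p, a chromosome arm whose genes were shifted up as a group in KO hTSC, as described below.

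In hTSC, 491 genes changed, 104 higher and 387 lower in KO cells, and 3267 had an unadjusted p under 0.05. Of the 10 pregnancy-specific glycoprotein genes, 8 fell and 2 did not pass (10 fell when adjusted over the list alone). A median of -2.83 was found over the whole list (adjusted p = 7.9e-19, and adjusted p = 0.0175 with an estimated correlation). Of 31 syncytiotrophoblast markers, 7 fell and 24 did not pass (20 fell when adjusted over the list alone). A median of -1.84 was found over the whole list (adjusted p = 1.8e-15, but adjusted p = 0.134 with an estimated correlation). DYSF (-2.64 ± 0.40), INHA (-3.94 ± 0.67), ERVV-2 (-1.83) and CGA (-2.73 ± 0.62) were among those that fell. Of 23 extravillous markers, 5 fell and 18 did not pass (11 fell when adjusted over the list alone). A median of -1.60 was found over the whole list (adjusted p = 4.1e-09, but adjusted p = 0.134 with an estimated correlation). Those that fell included ADAM12 (-4.01 ± 0.86), MMP2 (-2.65 ± 0.63), ITGA1 (-2.60 ± 0.54) and FN1 (fibronectin, -1.75 ± 0.45). In the cytotrophoblast list only EPCAM and TEAD4 rose, 0 fell and the list had an adjusted p of 0.219. Among chemokine genes, ACKR3, a scavenging chemokine receptor, fell from 0.809 to 0.0469 CPM and CCL5 from 0.777 to 0.0455 CPM, each with 3 counts over the KO group, and the list had an adjusted p of 0.07. Of 17 p53 target genes, TP53INP1 (-1.52 ± 0.35) and TNFRSF10B (-1.15 ± 0.29) fell and 15 did not pass (3 fell when adjusted over the list alone). A median of -0.95 was found over the whole list (adjusted p = 5.2e-06, but adjusted p = 0.248 with an estimated correlation). The naive pluripotency markers NLRP7 (2.31 ± 0.40) and DNMT3L (3.86 ± 1.02) rose and KLF4 fell (-1.53), LIN28A rose (1.22 ± 0.32), and in hTSC the naive and general pluripotency lists had adjusted p of 0.822 and 0.157, without a call. Other large rises were GSTM1, a glutathione transferase (4.97 ± 0.73), and HLA-A (2.64 ± 0.61), which shares reads with related genes, and other large falls were PHYHIPL (-5.06 ± 0.61) and NUDT19 (-4.20 ± 0.84). LNCPRESS1 had no counts in WT hTSC and 29 in KO hTSC, at least 9.42-fold higher from a floor of 3 counts over the WT group. Without at least 1 library, the calls of CGA, TEAD4, MMP2, FN1, CCL5, TP53INP1, TNFRSF10B, DNMT3L, KLF4, LIN28A and HLA-A were lost. The KO and WT libraries overlapped for MMP2, FN1, ACKR3, CCL5 and DNMT3L. Without hTSC WT replicate 1, HLA-A moved to 3.86 and GSTM1 to 9.42. Without hTSC WT replicate 2, NUDT19 moved to -3.42 and DNMT3L to 4.64. Without hTSC KO replicate 1, ADAM12 moved to -5.33 and CGA to -3.55, without hTSC KO replicate 2, MMP2 moved to -3.64, and without hTSC KO replicate 3, NUDT19 moved to -4.94. The count of 491 was 245 without hTSC WT replicate 3, 296 without hTSC KO replicate 2, 230 without hTSC KO replicate 3, 243 without hTSC KO replicate 4, 68 with the hTSC groups fitted alone and 968 in DESeq2. Replicates 1 and 2 alone gave 18 genes and replicates 3 and 4 alone gave 710.

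The comparison in EVT asked whether KO cells reached the extravillous state. Markers of extravillous trophoblast were lower in KO EVT and several markers of the stem-like layer were higher. FN1 fell 13.7-fold, from 388 ± 261 to 28.2 ± 13.6 CPM (n = 4 each, adjusted p = 4.2e-05), ITGA1, the laminin and collagen receptor of invading trophoblast, fell 10.1-fold, from 66.3 ± 38 to 6.61 ± 3.38 CPM (adjusted p = 0.000178), and the protease gene ADAM12 fell 11.3-fold, from 62.2 ± 25.9 to 5.46 ± 4.02 CPM (adjusted p = 4.5e-05). The gelatinase MMP2 fell 9.9-fold, from 1259 ± 692 to 127 ± 101 CPM (adjusted p = 0.00102, and 16.3-fold without EVT KO replicate 4). HLA-G, the class I molecule typical of EVT, was at 62.4 ± 66.7 CPM in KO and 552 ± 508 in WT cells (adjusted p = 0.0488), with overlapping libraries. It fell 1.72-fold in replicates 1 and 2 alone (adjusted p = 0.614) and 68.9-fold in replicates 3 and 4 alone (adjusted p = 0.000131). It kept its call only without EVT WT replicate 2 (11.2-fold) or EVT KO replicate 2 (17.6-fold), and the fold was 5.1 without EVT WT replicate 4. HLA-G and MMP2 were each chosen after its values were seen. ADAM12 was not specific to EVT, since every WT STB library lay above every WT EVT library. The extravillous list had a mean log2 CPM of 4.96 ± 0.13 in WT STB and 5.2 ± 1.2 in WT EVT. EPCAM rose 3.89-fold, from 36.3 ± 17.4 to 141 ± 19.9 CPM (adjusted p = 0.000903), and NRP2 rose 11-fold, from 2.2 ± 1.46 to 24.1 ± 12.6 CPM (adjusted p = 0.000524).

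In EVT, 1867 genes changed, 679 higher and 1188 lower in KO cells, and 4676 had an unadjusted p under 0.05. Of 23 extravillous markers, 17 fell and 6 did not pass (21 fell when adjusted over the list alone). A median of -2.82 was found over the whole list (adjusted p = 2.5e-21, and adjusted p = 0.0171 with an estimated correlation). The mean log2 CPM of the list lay between 2.01 and 3.09 in the KO libraries and between 3.47 and 5.87 in the WT libraries, where EVT WT replicate 2, at 3.47, stood apart from the others, which started at 5.63. Of 21 cytotrophoblast markers, 9 rose, 2 fell and 10 did not pass (11 rose and 2 fell when adjusted over the list alone). A median of 0.93 was found over the whole list (adjusted p = 3.8e-05, but adjusted p = 0.0666 with an estimated correlation). FGFR2 (1.69 ± 0.27), NRP2 (3.46 ± 0.58), EPCAM (1.96 ± 0.35) and TEAD4 (1.61 ± 0.31) were among those that rose. Of 25 matrix and protease genes, 7 fell and 18 did not pass (10 fell when adjusted over the list alone). A median of -1.58 was found over the whole list (-1.47 with bounds; adjusted p = 2.9e-06, and adjusted p = 0.0455 with an estimated correlation). Those that fell included the basement membrane genes COL4A1 (-2.44 ± 0.40), COL4A2 (-1.36) and LAMA4 (-4.04 ± 0.70) and the protease inhibitor TIMP1 (-2.92). Of 31 syncytiotrophoblast markers, 8 fell and 23 did not pass (10 fell when adjusted over the list alone). A median of -1.06 was found over the whole list (adjusted p = 8.7e-07, but adjusted p = 0.238 with an estimated correlation), led by the placental lactogen genes CSH1 (-4.92 ± 0.74) and CSH2 (-4.56 ± 0.85), which share reads. Of the 10 pregnancy-specific glycoprotein genes, 5 fell and 5 did not pass (6 fell when adjusted over the list alone). A median of -1.92 was found over the whole list (adjusted p = 8.2e-08, but adjusted p = 0.0984 with an estimated correlation). Of 23 interferon response genes, 10 fell and 13 did not pass (14 fell and 1 rose when adjusted over the list alone). A median of -1.58 was found over the whole list (-1.36 with bounds; adjusted p = 3.9e-05, but adjusted p = 0.238 with an estimated correlation). The genes that fell included ISG15 (-2.73 ± 0.40), IFI27 (-4.44), MX1 (-3.33) and IFIT1 (-2.56 ± 0.57). The WT libraries themselves differed in this list, with mean log2 CPM of 2.34, 3.83, 3.87 and 2.14 in replicates 1 to 4. Of 22 cell cycle genes, CCNB2 (0.73 ± 0.16), CCNA2 (0.78 ± 0.20) and CENPF (0.63 ± 0.18) rose and 19 did not pass at either adjustment (median 0.34, adjusted p = 0.000669, but adjusted p = 0.238 with an estimated correlation). Of 13 general pluripotency markers, LIN28A (2.10 ± 0.33) and L1TD1 (1.13 ± 0.30) rose and 11 did not pass (4 rose when adjusted over the list alone; median 0.06, or 0.36 with bounds; adjusted p = 0.00822, and adjusted p = 0.0481 with an estimated correlation). The WNT inhibitor NOTUM (-4.51 ± 0.74) and the receptor genes ACKR3 (-2.90 ± 0.54) and CCR1 (-1.86 ± 0.42) fell, and the chemokine gene CXCL14 rose (2.30 ± 0.64). WFDC2 (3.85 ± 0.43) and SLFN11 (4.50 ± 0.76) were among the largest rises, GSTM1 was at 6.78 CPM in KO and 0.026 in WT EVT, and TGFB2 at 0.0289 and 1.45 CPM. Without at least 1 library, the calls of CCNA2, CENPF, L1TD1 and CXCL14 were lost, and the KO and WT libraries overlapped for ITGA1, IFIT1, CCNA2, CCR1 and CXCL14. Without EVT KO replicate 4, CSH1 moved to -6.65, CSH2 to -6.71 and IFI27 to -5.20. Without EVT KO replicate 1, LAMA4 moved to -4.75, and without EVT WT replicates 1 to 4 in turn, NOTUM moved to -3.47, IFI27 to -3.75, CXCL14 to 3.05 and CSH2 to -3.58. The count of 1867 was 1190 without EVT WT replicate 4 and 1183 without EVT KO replicate 3. Replicates 1 and 2 alone gave 194 genes and replicates 3 and 4 alone gave 2015.

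**Figure D2:**
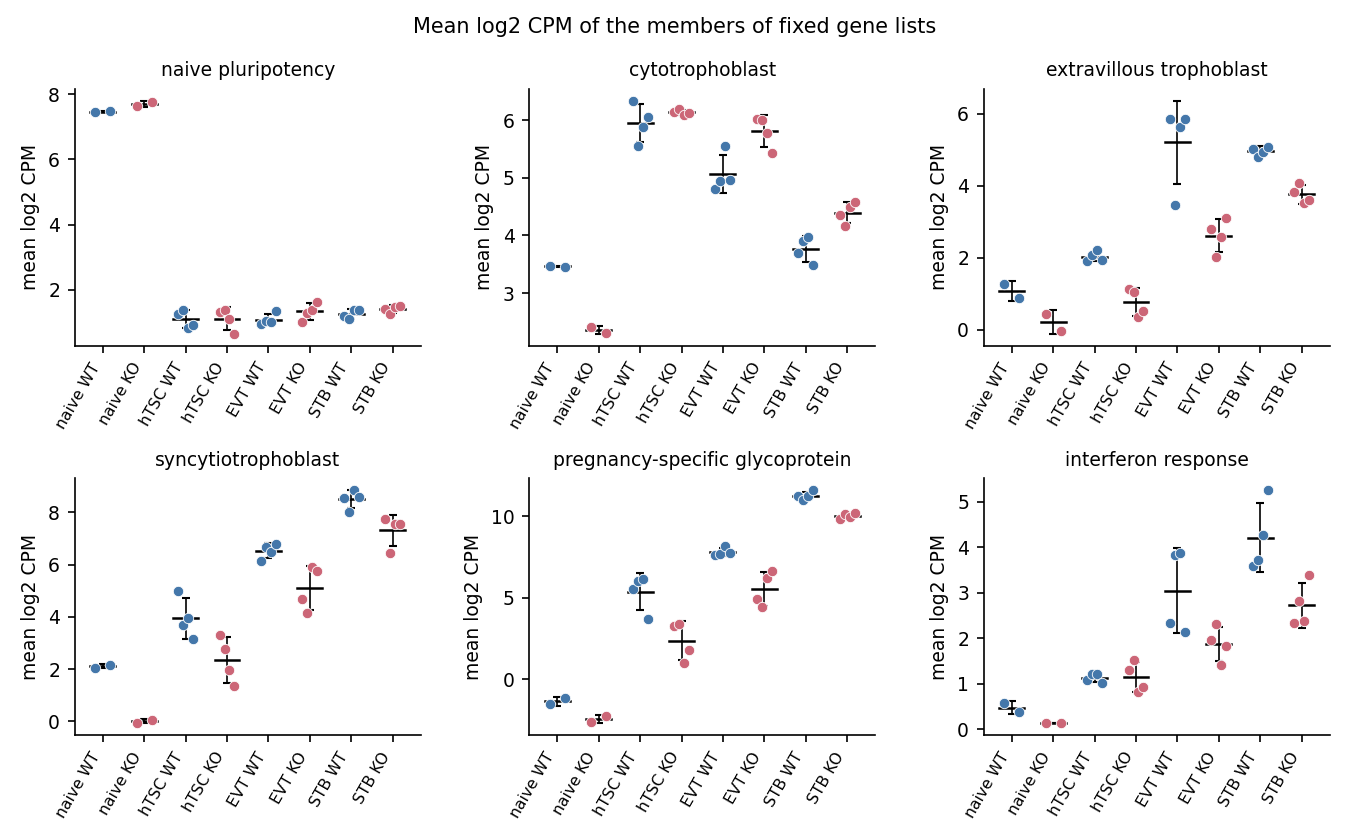
Mean log2 CPM over the members of 6 gene lists, with a point for each library (WT blue, KO red), a line at the group mean and a bar of 1 SD. The extravillous list lay between 2.01 and 3.09 in KO EVT and between 3.47 and 5.87 in WT EVT, and the pregnancy-specific glycoprotein, syncytiotrophoblast and extravillous lists were lower on average in KO than in WT cells of each trophoblast type.

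The comparison in STB asked whether KO cells formed syncytiotrophoblast. Of its 31 markers, 25 did not pass the test, while 10 of 23 interferon response genes and the fusion genes ERVFRD-1 and GCM1 were lower in KO cells. CYP19A1, the placental aromatase, was at 5104 ± 1680 CPM in KO and 6926 ± 1321 in WT cells (n = 4 each, log2 fold change -0.44 ± 0.74), SDC1 was at 285 ± 109 and 501 ± 250 (-0.82 ± 0.56) and CGA took 16 ± 5.85% and 25.2 ± 5.44% of all counts (-0.91 ± 0.59, adjusted p = 0.323). ERVFRD-1, which encodes the fusion protein syncytin-2, fell 12.9-fold, from 414 ± 209 to 32.1 ± 4.8 CPM (adjusted p = 0.00327), and GCM1, the transcription factor that drives fusion genes, fell 2.27-fold, from 1029 ± 244 to 453 ± 186 CPM (adjusted p = 0.00857). ISG15 fell 10.3-fold, from 464 ± 112 to 45 ± 30.5 CPM (adjusted p = 1.4e-05). EPCAM, which is low in WT STB, rose 12-fold, from 7.85 ± 2.33 to 94.6 ± 23.3 CPM (adjusted p = 3.3e-06).

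In STB, 2561 genes changed, 1506 higher and 1055 lower in KO cells, and 5534 had an unadjusted p under 0.05. Of 23 interferon response genes, 10 fell and 13 did not pass (14 fell when adjusted over the list alone). A median of -1.46 was found over the whole list (adjusted p = 1.5e-08, but adjusted p = 0.393 with an estimated correlation). The genes that fell included ISG15 (-3.36 ± 0.41), MX1 (-3.35), IRF9 (-2.57) and IFI6 (-1.93 ± 0.49). Of 31 syncytiotrophoblast markers, 6 fell and 25 did not pass, at either adjustment. A median of -0.91 was found over the whole list (adjusted p = 5.7e-05, but adjusted p = 0.711 with an estimated correlation). STB KO replicate 2 had a mean log2 CPM of 6.45 over these markers, below the other KO libraries at 7.55 to 7.75. Besides ERVFRD-1 and GCM1 the markers that fell included CSH1 (-2.07 ± 0.65) and CGB1 (-2.03 ± 0.62), each from a family with shared reads. Of the 10 pregnancy-specific glycoprotein genes, PSG6 (-1.34) and PSG7 (-4.27 ± 0.93) fell and 8 did not pass, at either adjustment (median -1.26, adjusted p = 0.0105, but adjusted p = 0.711 with an estimated correlation). Of 23 extravillous markers, FN1 (-2.78 ± 0.47), DIO2 (-3.44), EBI3 (-2.92) and HLA-G fell and 19 did not pass, at either adjustment (median -0.97, adjusted p = 5.7e-05, but adjusted p = 0.393 with an estimated correlation). The call of HLA-G rested on replicates 3 and 4 (-6.17, adjusted p = 0.000538), since replicates 1 and 2 alone gave -0.55 (adjusted p = 0.679). Of 17 p53 target genes, 6 fell and 11 did not pass, at either adjustment. A median of -0.91 was found over the whole list (adjusted p = 5.7e-05, but adjusted p = 0.393 with an estimated correlation). Those that fell included the death receptor gene TNFRSF10B (-1.36 ± 0.29), TP53INP1 (-1.27 ± 0.34), PLK3 (-1.37 ± 0.37) and AEN (-0.91 ± 0.26). Of 21 cytotrophoblast markers, 5 rose, 1 fell and 15 did not pass (7 rose and 2 fell when adjusted over the list alone). A median of 0.32 was found over the whole list (adjusted p = 0.0105, but adjusted p = 0.393 with an estimated correlation). EPCAM (3.58 ± 0.38), TEAD4 (1.56 ± 0.38) and VGLL1 (1.09) rose and TFAP2A fell (-0.71). The cell cycle genes CDK1 (0.84 ± 0.18), CCNA2 (0.97 ± 0.21) and CCNB2 (0.70 ± 0.17) rose and 19 of 22 did not pass (4 rose when adjusted over the list alone), and the list had no call (adjusted p = 0.316). The tight junction gene CLDN10 had the strongest evidence of a rise, from 0.998 ± 0.9 to 42.5 ± 11.5 CPM (5.36 ± 0.51, adjusted p = 4.4e-07), and PRAME (3.86 ± 1.08) and PAGE2 (4.87 ± 0.86), genes of the cancer-testis class, also rose. The receptor tyrosine kinase gene AXL (-3.84 ± 1.25), the amino acid transporter SLC6A19 (-3.82 ± 0.75) and the chemokine gene CXCL10 (-3.19 ± 0.85) fell. Without at least 1 library, the calls of IFI6, CSH1, CGB1, PSG6, TP53INP1, PLK3, AEN, PRAME, AXL and CXCL10 were lost, and the KO and WT libraries overlapped for CSH1, HLA-G, TEAD4, VGLL1, CDK1, CCNB2 and CXCL10. Without STB KO replicate 1, HLA-G moved from -4.42 to -5.20, EBI3 to -3.69, CSH1 to -2.75 and CXCL10 to -3.91. Without STB WT replicate 4, MX1 moved to -2.71, IFI6 to -1.20 and PRAME to 4.92. Without STB WT replicate 3, CLDN10 moved to 6.07 and PAGE2 to 6, and without STB WT replicate 2, AXL moved to -3.09. The count of 2561 was 1560 without STB WT replicate 2, 1515 without STB KO replicate 2 and 1204 with the STB groups fitted alone, where the balance turned to 573 higher and 631 lower. Replicates 1 and 2 alone gave 612 genes and replicates 3 and 4 alone gave 1120.

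**Figure D3:**
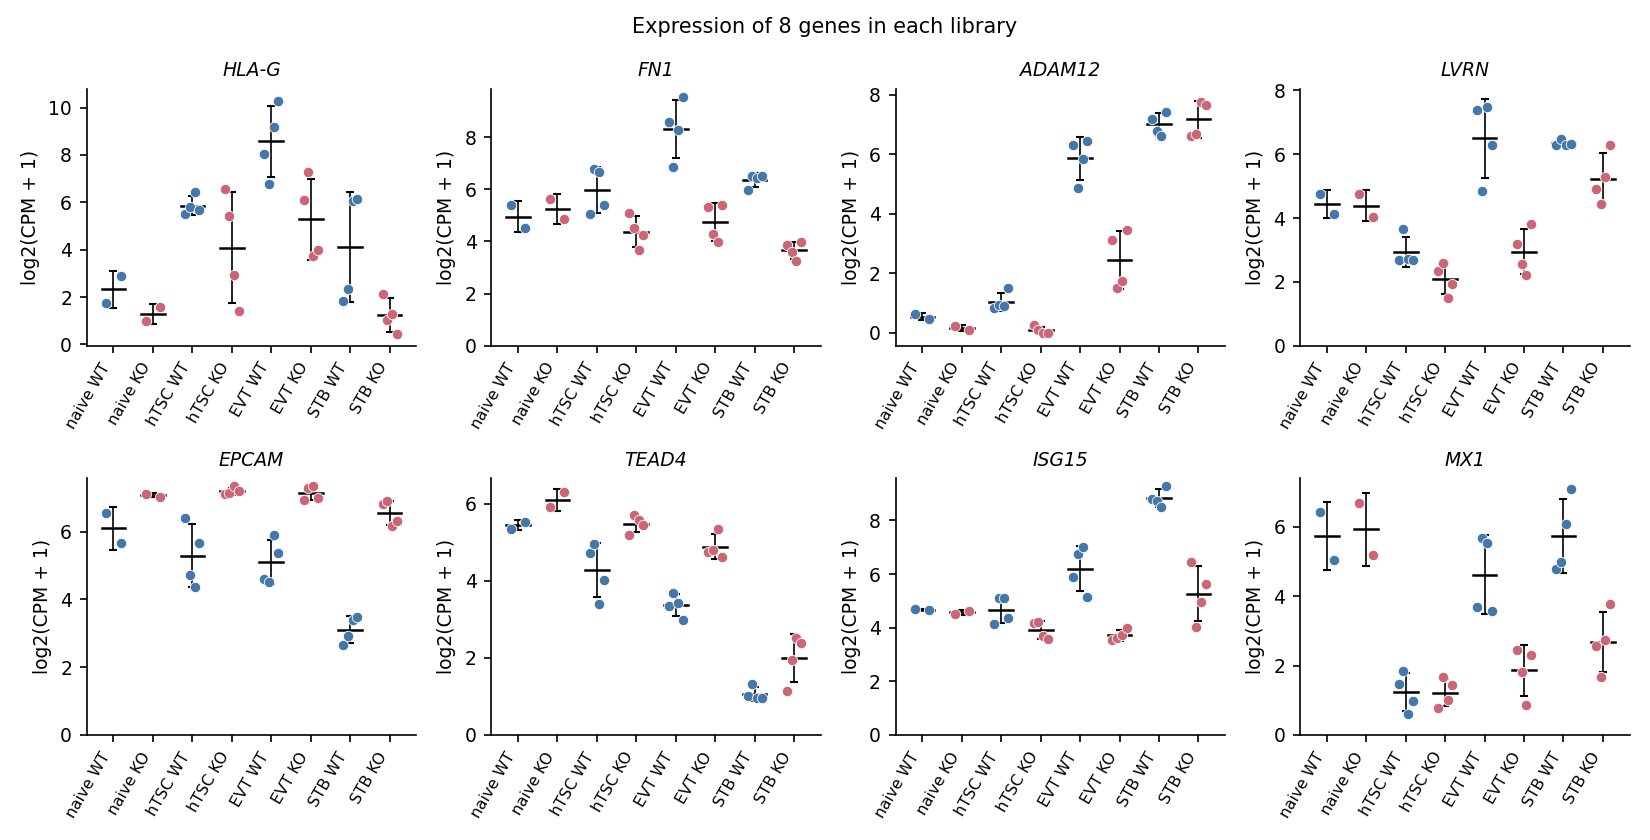
Expression of 8 genes as log2(CPM + 1), with a point for each library (WT blue, KO red), a line at the group mean and a bar of 1 SD. FN1 and ADAM12 fell 13.7-fold and 11.3-fold in KO EVT, EPCAM rose 3.25-fold in KO hTSC, 3.89-fold in KO EVT and 12-fold in KO STB, and ISG15 fell 10.3-fold in KO STB.

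None of the remaining fixed lists with a call in a KO comparison kept it with an estimated correlation. In naive KO cells, matrix and protease genes had 1 member that fell and 24 that did not pass (2 fell when adjusted over the list alone; median -0.32, adjusted p = 0.0195, but adjusted p = 0.289 with an estimated correlation). Integrins had 2 that fell and 12 that did not pass (3 fell and 1 rose when adjusted over the list alone; median -0.14, adjusted p = 0.0195, but adjusted p = 0.289 with an estimated correlation). No member of the p53 target list (median -0.35, adjusted p = 0.0344, but adjusted p = 0.539 with an estimated correlation) or the cholesterol synthesis list (median -0.36, adjusted p = 0.0195, but adjusted p = 0.515 with an estimated correlation) passed in naive cells at either adjustment. In KO hTSC, 2 of 14 integrins fell and 12 did not pass (5 fell and 1 rose when adjusted over the list alone; median -0.63, adjusted p = 0.00944, but adjusted p = 0.248 with an estimated correlation). No matrix and protease gene passed at either adjustment (median -0.72, adjusted p = 0.00547, but adjusted p = 0.248 with an estimated correlation), nor did any cell cycle gene (median 0.25, adjusted p = 0.00419, but adjusted p = 0.359 with an estimated correlation). SPRY2 fell among 15 ERK targets, with a call that was lost without any of 5 of the 8 libraries (2 fell when adjusted over the list alone; median -0.55, adjusted p = 0.0302, but adjusted p = 0.312 with an estimated correlation). The low density lipoprotein receptor LDLR, a gene of 19p, fell among 16 cholesterol synthesis genes (1 when adjusted over the list alone). Their median was -0.45 (adjusted p = 0.00567, but adjusted p = 0.359 with an estimated correlation). HLA-A rose among 12 antigen presentation genes (1 when adjusted over the list alone). Their median was 0.29 (adjusted p = 0.0299, but adjusted p = 0.248 with an estimated correlation).

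In KO EVT, 3 of 11 genes of epithelial-mesenchymal transition fell and 8 did not pass (4 fell when adjusted over the list alone; median -0.59, adjusted p = 0.0313, but adjusted p = 0.238 with an estimated correlation). Of 14 integrins, 4 fell, ITGB5 rose (a call lost without EVT WT replicate 4 or EVT KO replicate 2) and 9 did not pass (5 fell and 2 rose when adjusted over the list alone; median -0.67, adjusted p = 0.0333, but adjusted p = 0.238 with an estimated correlation). Of 17 p53 targets, 2 fell and 15 did not pass (6 fell when adjusted over the list alone; median -0.71, adjusted p = 0.00141, but adjusted p = 0.238 with an estimated correlation), and of 15 ERK targets, 3 fell and 12 did not pass (3 when adjusted over the list alone; median -0.72, adjusted p = 0.0118, but adjusted p = 0.238 with an estimated correlation). Of 16 cholesterol synthesis genes, 5 fell and 11 did not pass (5 when adjusted over the list alone; median -0.32, adjusted p = 0.0041, but adjusted p = 0.251 with an estimated correlation). None of the 11 mitochondrially encoded genes passed at either adjustment (median 0.41, adjusted p = 0.0438, but adjusted p = 0.613 with an estimated correlation). The other 15 lists had no call in any KO comparison, with a lowest adjusted p of 0.0685 for Notch genes, and the genes that neighbour CCR7 on chromosome 17 had a lowest adjusted p of 0.463. Some of them passed under other settings. With only the groups compared these were naive pluripotency in naive cells (adjusted p = 0.0267) and chemokine (adjusted p = 0.00909) and blood and endothelium genes (adjusted p = 0.0234) in EVT, and with the replicate block WNT genes in hTSC (adjusted p = 0.0231). Without genes of 12p, 17p and 19p they were chemokine genes in naive cells (adjusted p = 0.0238) and Notch genes in EVT (adjusted p = 0.0475). The replicate block also removed calls. In naive cells these were matrix and protease genes (adjusted p = 0.0884), integrins (adjusted p = 0.0588) and p53 targets (adjusted p = 0.0509). In EVT they were epithelial-mesenchymal transition (adjusted p = 0.0649), integrins (adjusted p = 0.0787) and mitochondrially encoded genes (adjusted p = 0.0711).

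The WT cells gave the reference for each differentiation step. From naive cells to hTSC, 12 of 13 naive pluripotency markers fell (median -7.66, adjusted p = 1.1e-23) and 16 of 21 cytotrophoblast markers rose and 1 fell (median 2.52, adjusted p = 1.3e-10), and both lists kept their call with an estimated correlation (adjusted p = 2.4e-08 and adjusted p = 0.00491). DPPA5 (-13.76) and POU5F1 (-11.26) were among the falls, and VGLL1 (4.79), EGFR (4.59), PSG3 (9.69) and PSG6 (8.53) among the rises. From hTSC to EVT, 20 of 23 extravillous markers rose and 0 fell (median 3.24, adjusted p = 4.4e-23, and adjusted p = 0.0132 with an estimated correlation), with DIO2 (7.79), MMP2 (6.44), ADAM12 (5.81) and LVRN (4.02) among them. Of the cytotrophoblast markers, 10 fell and 2 rose (median -0.89, adjusted p = 0.00062, but adjusted p = 0.141 with an estimated correlation). From hTSC to STB, 30 of 31 syncytiotrophoblast markers rose (median 3.98, adjusted p = 3.6e-17, but adjusted p = 0.0565 with an estimated correlation), with INHA (6.76) and DYSF (3.38) among them, and 19 of 22 cell cycle genes fell (median -1.68, adjusted p = 1.1e-15, and adjusted p = 0.0318 with an estimated correlation), with MKI67 (-3.04) and PLK1 (-3.65) among them. Interferon response genes rose in both steps, 15 of 23 in EVT (median 2.44, adjusted p = 2.1e-10, but adjusted p = 0.141 with an estimated correlation) and 18 of 23 in STB, where 1 fell (median 3.91, adjusted p = 4e-08, but adjusted p = 0.146 with an estimated correlation). Adjusted over the list alone, the counts were 12 for naive pluripotency, 16 higher and 1 lower for cytotrophoblast in hTSC, 20 for extravillous markers, 3 higher and 11 lower for cytotrophoblast in EVT, 30 for syncytiotrophoblast, 19 for cell cycle, 16 for interferon response in EVT, and 18 higher and 1 lower for interferon response in STB. In all, 7428 genes changed from naive cells to hTSC (3672 higher, 3756 lower), 2978 from hTSC to EVT (1428 higher, 1550 lower) and 8685 from hTSC to STB (3917 higher, 4768 lower). For STB the larger direction turned with the scaling, to 4466 higher and 4214 lower with RLE factors, which moved the median gene by 0.11, and to 4556 and 4289 in DESeq2. For hTSC it turned under 7 of 15 settings, among them DESeq2 (3811 higher, 3604 lower) and the filter of 1 CPM in 4 libraries (3443 higher, 3183 lower). For EVT it turned without EVT WT replicate 1 (1227 higher, 1208 lower) and in replicates 3 and 4 alone (1489 higher, 1200 lower), so the larger direction was left open for all 3 steps. The first count was 4928 without naive WT replicate 1, the second was 1958 without EVT WT replicate 4, and replicates 1 and 2 alone gave 535 for EVT and 4873 for STB.

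Further fixed lists moved in the WT steps. From naive cells to hTSC, 10 of 10 pregnancy-specific glycoprotein genes (median 8.30, adjusted p = 9.6e-10, but adjusted p = 0.0622 with an estimated correlation), 15 of 31 syncytiotrophoblast markers (adjusted p = 0.000287, but adjusted p = 0.451 with an estimated correlation), 10 of 14 integrins (adjusted p = 0.000117, but adjusted p = 0.0622 with an estimated correlation) and 11 of 16 cholesterol synthesis genes (adjusted p = 0.000407, but adjusted p = 0.315 with an estimated correlation) rose. So did 11 of 15 ERK targets (adjusted p = 4.1e-07, and adjusted p = 0.0188 with an estimated correlation), while 11 of 13 general pluripotency markers fell (median -7.11, adjusted p = 1.4e-23, and adjusted p = 9.8e-08 with an estimated correlation) and 10 of 19 hypoxia genes fell (adjusted p = 0.00462, but adjusted p = 0.414 with an estimated correlation). From hTSC to EVT, 15 of 31 syncytiotrophoblast markers (median 1.75, adjusted p = 1.3e-15, but adjusted p = 0.13 with an estimated correlation), 8 of 10 pregnancy-specific glycoprotein genes (median 2.14, adjusted p = 4.9e-09, but adjusted p = 0.13 with an estimated correlation) and 3 of 6 blood and endothelium genes (adjusted p = 0.0489, but adjusted p = 0.287 with an estimated correlation) rose. From hTSC to STB, 10 of 10 pregnancy-specific glycoprotein genes (median 5.69, adjusted p = 4.9e-12, but adjusted p = 0.0532 with an estimated correlation), 15 of 23 extravillous markers (median 2.44, adjusted p = 1.2e-07, but adjusted p = 0.135 with an estimated correlation) and 11 of 15 stress response genes (median 1.79, adjusted p = 6.8e-05, but adjusted p = 0.203 with an estimated correlation) rose. There, 14 of 21 cytotrophoblast markers (median -2.50, adjusted p = 1.8e-06, but adjusted p = 0.0532 with an estimated correlation), 10 of 18 imprinted genes (median -2.19, adjusted p = 0.00248, but adjusted p = 0.135 with an estimated correlation) and 6 of 12 WNT genes (adjusted p = 0.048, but adjusted p = 0.146 with an estimated correlation) fell. Adjusted over the list alone, the counts were 10, 16, 10, 12, 13, 11 and 10 in hTSC, 21, 9 and 3 in EVT, and 10, 15, 11, 14, 10 and 6 in STB, in the order given.

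Genes of each differentiation step were then compared between genotypes at its end. The 200 genes that rose most from WT hTSC to WT EVT were lower in KO EVT, with a median log2 fold change of -2.22, and 106 of them were called lower and 2 higher (camera p = 4.5e-35, and p = 6.8e-05 with an estimated correlation). With the genes chosen in a pair of WT EVT libraries and KO compared with the remaining pair, which keeps each WT EVT library out of the other use, the medians were -1.85 and -1.58. The 200 genes that fell most in that step had a median of 0.78 (15 higher, camera p = 5.6e-05, and p = 0.0417 with an estimated correlation), and with separate libraries 0.10 (p = 0.522) and 0.26 (p = 0.031, but p = 0.263 with an estimated correlation). In STB, the 200 rising genes had a median of -0.82 (41 lower, 3 higher, camera p = 2.4e-09, and p = 0.00429 with an estimated correlation), and with separate libraries -0.61 and -0.57. The 200 falling genes had a median of 1.64 (26 higher, camera p = 2.4e-07, and p = 0.0039 with an estimated correlation), and with separate libraries 0.75 (p = 0.00672, but p = 0.0842 with an estimated correlation) and 0.22 (p = 0.569).

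The change over each step was also compared between genotypes directly, as an interaction. From naive cells to hTSC, 16 genes differed, 15 with a larger rise in KO cells and 1 with a smaller one, and 1087 had an unadjusted p under 0.05. The cytotrophoblast transcription factors GATA2 (2.77 ± 0.36), GATA3 (2.33 ± 0.37) and MSX2 (2.98 ± 0.58) and the cofactor VGLL1 (3.12 ± 0.45) were among the 15, since they were lower in naive KO cells and GATA3, for example, was at 124 ± 26 CPM in KO and 117 ± 13.9 in WT hTSC. The count was 9 without naive WT replicate 2, 4 without either naive KO replicate 1 or naive KO replicate 2, 30 without hTSC WT replicate 1, 25 without hTSC KO replicate 1 and 68 in DESeq2. From hTSC to EVT edgeR called 0 genes, with 1115 at an unadjusted p under 0.05, and DESeq2 called 27. The edgeR count was 13 without EVT WT replicate 2, 1 without hTSC WT replicate 4 and 1 without EVT WT replicate 3. The extravillous markers as a list had a median interaction of -1.57 (adjusted p = 3.7e-08, but adjusted p = 0.155 with an estimated correlation). From hTSC to STB edgeR called CLDN10 alone (4.50 ± 0.63, adjusted p = 0.0021), with 1828 genes at an unadjusted p under 0.05, and DESeq2 called 79. That count was 4 without hTSC WT replicate 4, 3 without hTSC WT replicate 1 or STB KO replicate 4, and 2 without hTSC KO replicate 1, hTSC KO replicate 4, STB KO replicate 1 or STB KO replicate 3.

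Genes changed in the same direction recurred across the trophoblast types, between which no library was shared. All KO libraries share a name prefix, so another trait of a shared KO line would recur as well. EPCAM, TEAD4, LIN28A, NLRP7, GSTM1 and WFDC2 were among 53 genes higher in KO hTSC, EVT and STB, and FN1, ACKR3, TP53INP1, LDLR and PSG6 were among 135 lower in each of them. Only CCR7, PGF and LCMT1-AS2 were lower in all 4 cell types. Of the genes lower in KO, hTSC and EVT shared 242, against 23.6 for independent lists (Fisher's exact test, adjusted p = 6.5e-198), hTSC and STB shared 184 against 20.9 (adjusted p = 1.8e-129), and EVT and STB shared 348 against 64.3 (adjusted p = 2.6e-171). Of the genes higher in KO, the shared counts were 69 against 3.62 (adjusted p = 3.6e-75), 72 against 8.03 (adjusted p = 2e-55) and 333 against 52.4 (adjusted p = 4.9e-193). Without genes of the chromosome arms described next, the shared lower genes numbered 129, 78 and 206. Many of the 135 genes lower in each type, LDLR among them, lie on 17p or 19p, and TEAD4 lies on 12p. The counts of 53 and 135 were not repeated without those arms.

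Because lines of stem cells can differ in chromosome content, fold changes were also summarised along chromosome arms, and the arms 12p, 17p and 19p were chosen after the data were seen. Genes of the short arms of chromosomes 17 and 19 were lower in KO trophoblast cells of each type. The median log2 fold change over 331 genes of 17p was -0.85 in hTSC, -0.80 in EVT and -0.88 in STB, and over 593 genes of 19p it was -0.49, -0.52 and -0.63. In naive cells the same medians were 0.0046 and -0.03. The medians of the long arms 17q and 19q in trophoblast cells lay between -0.20 and -0.05. On 17p every KO library lay below every WT library of its trophoblast type, and on 19p the exception was hTSC WT replicate 1, at -0.21 from the centre of its cell type. These arms held 4.74% of the genes tested and 30% of the genes called lower in hTSC (116 of 387), 16.8% in EVT (200 of 1188) and 23.3% in STB (246 of 1055). On 12p, the median over 289 genes was shifted up in KO cells, at 0.39 in naive cells, 0.38 in hTSC, 0.36 in EVT and 0.54 in STB. Of these genes, 0, 7, 27 and 50 were called higher, in that order, and 5 were called lower in EVT. The naive median was 0.20 without naive KO replicate 1. In the trophoblast types the 12p difference came from replicates 3 and 4, in which the 12p median over expressed genes was 0.79 in hTSC, 0.80 in EVT and 1.05 in STB, while in replicates 1 and 2 it was -0.10, -0.08 and 0.10. Each of the shifts of 17p, 19p and 12p in trophoblast cells, and of 12p in naive cells, had a p of 1e-04. This is the smallest that 10000 random gene sets can give, with an adjusted p of 0.00078 over 156 tests (39 arms in 4 cell types). The sets were drawn from the genes of the same comparison, so this p measures spread over genes, not over libraries. In the trophoblast types 12p reached it although replicates 1 and 2 had no such shift. Other arms shifted less but passed as well. In all, 7 arms were past the threshold in naive cells, 12 in hTSC, 12 in EVT and 11 in STB. Those with the same smallest p were 1q in naive cells (-0.29) and hTSC (-0.14), 3p in naive cells (0.08) and 4q in hTSC (0.09) and STB (0.205). So were 5p in EVT (-0.31), 17q in hTSC (-0.20), EVT (-0.14) and STB (-0.18), and 19q in STB (-0.17). In hTSC the 1q shift came from WT replicate 1, at 0.31 from the centre over expressed genes. The other WT libraries lay between -0.0245 and -0.000639 and the KO libraries between -0.0612 and -0.00742. The p53 gene TP53, chosen after its values were seen, lies on 17p and was at 15.6 ± 4 CPM in KO and 23.8 ± 4.82 in WT STB (log2 fold change -0.61 ± 0.23, adjusted p = 0.0833). TEAD4 lies on 12p, and its rise in replicates 3 and 4 cannot be told apart from that of the arm. In replicates 1 and 2 the arm had no such shift. There TEAD4 was at 4.742 and 4.792 log2(CPM + 1) in KO and 3.35 and 3.688 in WT EVT. In hTSC these values were 5.193 and 5.695 against 4.717 and 4.942, and in STB 1.141 and 1.935 against 1.022 and 1.315. Without genes of 12p, 17p and 19p, 294 genes were changed in hTSC.

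**Figure D4:**
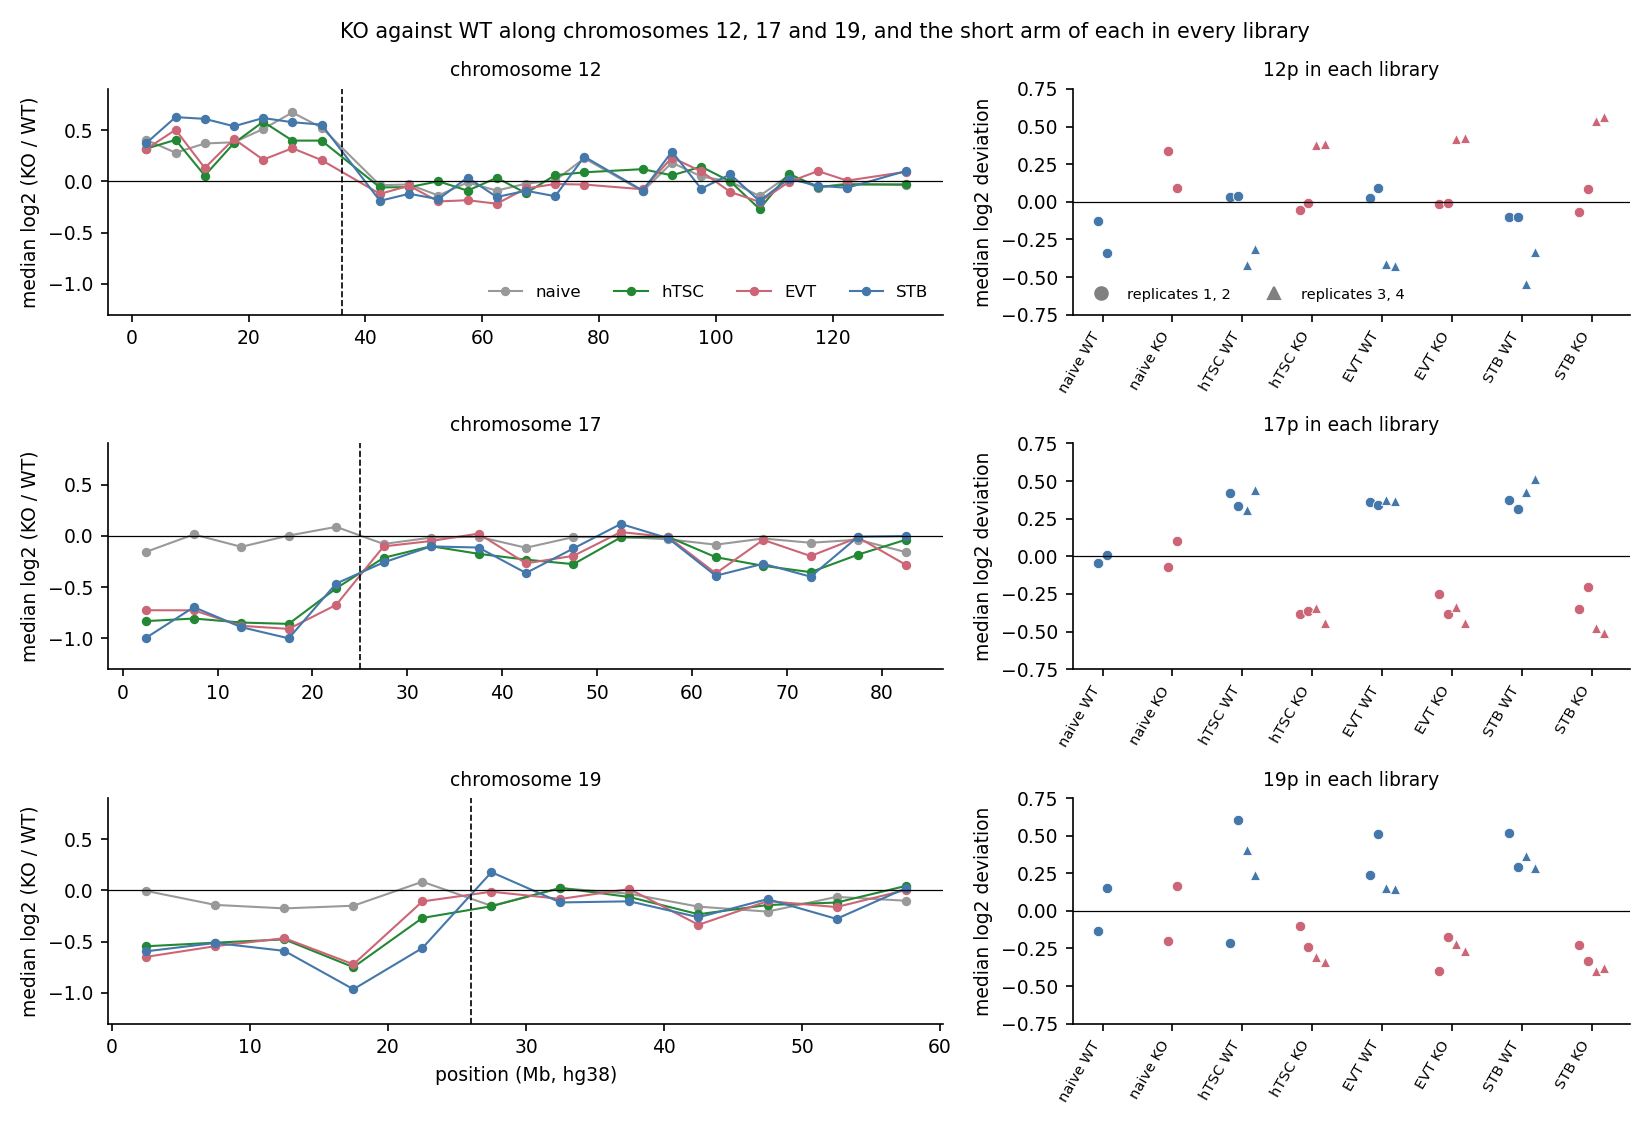
Left, median log2 fold change of KO over WT in bins of 5 Mb with at least 5 genes along chromosomes 12, 17 and 19 in each cell type, with a dashed line at the boundary between the arms. Right, the median over expressed genes of 12p, 17p and 19p in each library, as the log2 deviation from the centre of its cell type (WT blue, KO red, circles for replicates 1 and 2 and triangles for 3 and 4); in hTSC the 12p difference was -0.10 in replicates 1 and 2 and 0.79 in replicates 3 and 4.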

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

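The tests of copy number for the arm shifts, of CCR7 loss acting in every cell type and of a 12p difference shared by all cultures were chosen only after the result was seen. The other tests in this part were fixed before their results were known.

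Dixon's test picked out 7 of 210 combinations of group and measure, and chance alone flags about 1 in 20 groups. Values are mean log2 CPM for lists. In hTSC KO replicate 1 the hypoxia list was at 6.39 (others 5.14 to 5.28) and the stress response list at 6.54 (others 4.92 to 5.02). EVT WT replicate 2 had the extravillous list at 3.47 (others 5.63 to 5.87) and a total, in units of 1e+06 counts, of 31.8 (others 15.8 to 18.3). STB WT replicate 1 had 9.88% of its counts on mitochondrial genes (others 3.75 to 4.6). STB KO replicate 2 had the fibroblast list at 0.901 (others 1.18 to 1.22) and the syncytiotrophoblast list at 6.45 (others 7.55 to 7.75).

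The change from naive cells to hTSC differed between genotypes, by the interaction test, in 16 genes. On the log2 scale the differences were GJA5 3.28, IL36RN 5.46, ACKR2 1.68, GATA2 2.77, SLC27A6 3.27, MSX2 2.98, DLX5 3.76, GATA3 2.33, CPM 3.47, PCLAF 3.28, SP6 3.21, STS 2.39, CAPN6 3.72, VGLL1 3.12 and TLE2 -3.71, and the fitted value of CD274, which depends on a group without counts and is no bound, was 7.64. The cytotrophoblast list differed by a median of 1.25 and the syncytiotrophoblast list by 1.33, and only the cytotrophoblast list kept its call with an estimated correlation (adjusted p = 0.000282 against adjusted p = 0.965).

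The pattern behind the positive values among these is the lower level of trophoblast genes in naive KO than in naive WT cells, n = 2 each. It does not cover TLE2, which had the opposite sign. Reads carried over from other libraries would enter both genotypes alike, and the share of the hTSC level in KO was 0.239 of that in WT, which argues against them. A small number of trophoblast-like cells in the naive WT cultures may explain the pattern. Of 100 abundant hTSC genes, 75% were higher in both naive WT libraries than in both naive KO libraries (chance 16.7%), where 80% had been set as the mark, so this explanation and an effect of CCR7 loss cannot be told apart. The median share of the hTSC level in naive WT was 3.03% (quartiles 1.51 to 4.58%), with CCR7 itself at 3% and CGA at 13.6%.

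From hTSC to EVT edgeR called 0 genes (1115 at an unadjusted p under 0.05, and 27 called in DESeq2), but 8 lists differed in the test with the preset correlation, and none kept its call with an estimated correlation (lowest adjusted p = 0.155). Their medians were 0.468 for cytotrophoblast, -1.57 for extravillous trophoblast, 0.586 for syncytiotrophoblast, 1.13 for pregnancy-specific glycoproteins, -1.57 for interferon response, -0.76 for antigen presentation, -0.609 for matrix and protease and -0.446 for WNT genes. From hTSC to STB, CLDN10 differed by 4.50, and 5 lists did, again without a call under an estimated correlation (lowest adjusted p = 0.266), at 0.828 for syncytiotrophoblast, 1.61 for pregnancy-specific glycoproteins, -1.96 for interferon response, 0.752 for matrix and protease and 0.516 for integrins.

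The lower level in KO EVT of genes that rise from WT hTSC to WT EVT was weighed as a second pattern. A larger share of hTSC-like cells in the KO cultures would undo rises and falls alike, but the median lost share was higher for rising than for falling genes by at least 0.52, which argues against it as the whole cause. Of the 200 rising genes, 6 lay on 12p, 17p and 19p, and the other 194 had a median of -2.20. Leaving out so few genes could hardly move the median, so the preset mark decided little. Copy number of those arms is opposed only as a direct cause for the 194 genes outside them, and an indirect effect was not tested. An effect of the knockout, or of another difference between the KO and WT cultures, stays open.

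The lower level of 17p and 19p genes and the higher level of 12p genes in KO trophoblast cells was the third pattern, and after removal of a trend over GC content and length, the medians closest to 0 were -0.43 for 17p and 19p and 0.34 for 12p, which argues against such a bias. Loss of CCR7 acting in every cell type is opposed for 17p by its naive median of 0.0046. For 19p it stays open, as the naive median of -0.0311 ranged from -0.276 to 0.212 without single libraries. CCR7 was at 6 CPM in naive WT cells, against 200, 213 and 139 in hTSC, EVT and STB. With so little to lose, naive cells leave an effect confined to trophoblast cells open. For 12p the naive median was like the others. In replicates 1 and 2 of the trophoblast types CCR7 was low in KO as well, at most 4.07 CPM. The 12p medians there were -0.10, -0.08 and 0.10, which argues against CCR7 loss alone as the cause at 12p in those types. A difference in copy number between the KO and WT cultures is a candidate explanation, since at least 77.1% of the genes of each arm lay on the shifted side and 12q, 17q and 19q stayed within 0.165 of the genome median over all replicates. A shift that ends at the centromere was not seen in every culture. In replicates 1 and 2 the median was -0.27 in hTSC and -0.28 in EVT for 17q and -0.23 and -0.22 for 19q. In replicates 3 and 4 these were -0.02, -0.01, 0.03 and 0.04. In STB the replicate sets differed less, at -0.155 and -0.10 for 17q and -0.19 and -0.108 for 19q. The short arms in replicates 1 and 2 lay lower still, with 17p at -0.73 in hTSC and -0.66 in EVT and 19p at -0.40 and -0.69. For 12p a copy number difference would not be shared by all cultures, as the median in replicates 1 and 2 lay no farther from 0 than -0.10, and no DNA was measured.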

How the results depend on the processing

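The fits of replicates 1 and 2 or of replicates 3 and 4 alone, the fits without genes of 12p, 17p and 19p, and all arm values were chosen after seeing the data. No call of a named gene, of a fixed list or of the genes of a differentiation step changed direction under any alternative run. The 12p median did, from 0.38 to -0.10 in hTSC and from 0.36 to -0.08 in EVT, in replicates 1 and 2 alone over expressed genes. The larger direction in STB also turned, from 1506 higher and 1055 lower to 573 and 631 with only the groups compared. RLE factors and the stricter filter left every count within 1.5 times its value, though not always the larger direction, and the cause of the other changes was not tested. DESeq2 gave 128 genes in naive cells (62 in edgeR), 968 in hTSC (491), and for the interactions 68 from naive cells to hTSC (16), 27 from hTSC to EVT (0, with 1115 at an unadjusted p under 0.05 in edgeR) and 79 from hTSC to STB (1). With only the groups compared, naive cells gave 20, hTSC 68, STB 1204 and the interaction to STB 3, and CCR7 in naive cells was at -4.12 (adjusted p = 0.136). The term for replicates 1 and 2 against 3 and 4 gave interaction counts of 30, 1 and 6, and no filter gave 1 to EVT. Replicates 1 and 2 alone gave 18 genes in hTSC, 194 in EVT, 612 in STB, 535 and 4873 for the WT steps to EVT and STB, and 0 for the interaction to STB. Replicates 3 and 4 alone gave 1120 in STB and interaction counts of 10 to EVT and 6 to STB. With an absolute log2 fold change of at least 1, STB gave 1507, and the overlaps were 37 (hTSC and EVT, higher), 46 and 121 (hTSC and STB, higher and lower), and 137 and 222 (EVT and STB). Without the 3 arms, hTSC gave 294, and the overlaps of lower genes were 129, 78 and 206. Falling genes of the EVT step had a median of 0.10, and those of the STB step 0.22, with lists from separate libraries. Over genes with a mean log2 CPM of at least 3, 19p in naive cells was at -0.11.

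With the replicate number as a replicate block, naive cells gave 103 genes, the interactions 48, 13 and 2, and the overlaps of higher genes 112 (hTSC and EVT) and 118 (hTSC and STB). Same-numbered KO and WT libraries correlated best in all 4 numbers of hTSC. In EVT this held only for replicates 2 and 4, and in STB only for replicate 3. In naive cells it held for both numbers (0.5 against -0.5), but with 2 libraries per group these values are mirror images by construction. Nothing in the labels pairs the libraries.

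Leaving out each library in turn gave 16 to 30 genes in naive cells, 230 to 547 in hTSC, 1183 to 1559 in EVT and 1515 to 2310 in STB. The WT steps ranged from 4928 to 7082, 1958 to 2849 and 7869 to 8185, and the interactions from 4 to 30, 0 to 13 and 1 to 4. A naive group left with a single library is assumed to vary like the other groups. CCR7 ranged from -4.61 to -3.29 in naive cells, -7.12 to -6.28 in hTSC, -6.51 to -6.07 in EVT and -6.00 to -5.43 in STB. The 12p median ranged from 0.20 to 0.53 in naive cells, 0.29 to 0.43 in hTSC, 0.25 to 0.47 in EVT and 0.43 to 0.61 in STB. That of 17p ranged from -0.0936 to 0.0892, -0.89 to -0.82, -0.86 to -0.77 and -0.99 to -0.85, and that of 19p from -0.28 to 0.21, -0.63 to -0.40, -0.56 to -0.36 and -0.67 to -0.57.

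Of the named genes, 148 of 568 missed the threshold without some library, 84 of 518 with only the groups compared, 214 of 412 in replicates 1 and 2 alone, 79 of 416 in replicates 3 and 4 alone and 10 of 565 in DESeq2. Of 77 list calls, 64 were lost and 13 kept with an estimated correlation (32 of 38 lost in KO comparisons, 18 of 24 in WT steps and 14 of 15 in interactions). With only the groups compared, 15 pairs of list and comparison gained a call. In simulated data, 4-fold changes were recovered for 36.4% of genes in naive cells, 57.6% in hTSC, 54.5% in EVT and 66.7% in STB. In the interactions the shares were 25.8, 33.3 and 30.3%. For 2-fold changes they were 1.49, 17.9, 10.4 and 8.96% in the 4 KO comparisons, so small changes were mostly missed in the simulations. Each simulation held 200 changed genes, fewer than were called in hTSC, EVT or STB, so recovery in the real data may have differed.

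Among regroupings of the libraries, the real one gave the most genes in hTSC (491, highest other 46), EVT (1867, highest other 187) and STB (2561, highest other 5). The same held for the WT steps to EVT (2978, highest other 132) and STB (8685, highest other 1). In each case 1 of 35 groupings, the real one, gave as many, and 35 groupings allow no smaller share. Chance was thus made less likely but not excluded. Mixed groups also carry the real difference as spread, which lowers their counts. For the interaction to STB, 13 of 100 groupings were as large (1 in edgeR, highest other 534), so chance was not made less likely. For the interaction to EVT the count in edgeR was 0, so 100 of 100 groupings were as large by construction and the regrouping says nothing about chance (highest other 633). The counts of 633 and 534 point to a structure of the libraries. Each came from the only grouping in which the numbers of KO libraries placed in the KO group differed by 3 between the cell types, and groupings in which they differed by at most 1 gave at most 3 genes.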

Other observations

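The genes in this part were chosen after their values were seen, and no explanation was tested for them.

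In STB the chemokine gene CCL28 rose (1.41) and ACKR3 fell (-2.02), and the chemokine list had no call.

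The imprinted gene SNRPN rose in KO STB (4.55, and 6.53 without STB WT replicate 2), while its call in hTSC was lost without any of 7 of the 8 libraries. The transcript NLRP9 had no counts in KO EVT and 99 in WT EVT, which makes it at least 22.4-fold lower from a floor of 3 counts over the KO group. In STB, GSTM1 had no counts in WT and 77 in KO, at least 22.9-fold higher.

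CGA took 0.126% of all counts in KO hTSC and 0.913% in WT hTSC. Its change in EVT had no call (adjusted p = 0.377). There, KO replicates 3 and 4 (2.51 and 1.92%) were near the WT libraries (1.93 to 3.06%) and only KO replicates 1 and 2 were low (0.542 and 0.269%). Outside STB, the gene with the most counts took at most 3.06% of a library, and in STB CGA took between 11.4 and 31.5%.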
